A study of Mus musculus with 30 samples.

How the data were processed

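DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads CpG-rich fragments cut from genomic DNA, in cauda epididymal sperm of 30 male C57BL/6J mice. Per the labels, 15 mice drank reverse-osmosis water with 0.9 ppm cadmium, made from cadmium chloride, and 15 drank the water alone. The mice were 7 weeks old at the start and were sampled after 9 weeks of treatment, and the average dose was 0.68 mg cadmium per kg of body weight.

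The deposited tables hold, for each cytosine of a CpG and each strand, the count of covering reads and the fraction of them that was methylated. The submitters' processing notes name bcl2fastq, Trim Galore 0.5.0, Bismark 0.22.3 and methylKit 1.12.0 and the builds mm10 and GRCm38; the role of each tool is not given in the sources used here. The fraction multiplied by the deposited count was whole within 0.1 for all but at most 1 cytosine of each library, so methylated reads were taken as the rounded product. No minimum coverage had been applied to the deposited counts. Coverage summed over cytosines was 53591172 to 94090975 per library. A read covers several CpGs and PCR copies are not separate molecules, so coverage overstates the number of DNA molecules, and intervals that rest on counts cover counting error only. The methylated control sequence in the libraries read 97.9% to 98.7% methylated and the unmethylated one 0.074% to 0.666%.

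Both strands of a CpG were summed. A CpG was tested on the autosomes and X with 10 or more reads in at least 10 mice of each group, after leaving out CpGs above the 99.9th percentile of a mouse's coverage, which was taken over the CpGs with 5 or more reads in at least 20 mice. Methylated and unmethylated reads were compared between groups with a logistic model, with the Pearson dispersion never below 1 and an F test of treatment. P values were adjusted by the Benjamini-Hochberg method, and a call needed an adjusted p under 0.05. The same model was used on reads summed over regions of 3 or more CpGs, each 100 bp or less from the next, and over gene ends. Differences are in percentage points between the unweighted means of the mice.

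The annotation used, RefSeq genes on GRCm38, gives the start and end of 34337 protein-coding, lncRNA and antisense genes but neither strand nor exons. The planned promoter windows were therefore replaced by the window of 1000 bp either side of the gene end, of both ends of a gene, that held more tested CpGs, chosen without regard to treatment or methylation. These gene ends are often, but not always, promoters. The 19066 gene ends with 3 or more CpGs covered 17189 distinct sets of CpGs, so neighbouring genes share values. Exon and intron contexts were replaced by gene body, and the H19 control region was placed 2000 to 4000 bp beyond the H19 end that faces Igf2.

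Global methylation was the unweighted mean over the 416876 CpGs with 10 or more reads in every mouse. This mean, the means of 8 contexts, 13 gene lists and the imprinted regions were compared by two-sided permutation tests with 100000 resamples, adjusted within the contexts and within the lists. Intervals of differences are at 95%. The maternal germline DMR level was the mean over the 13 gene ends of the maternal list that were measured in every mouse and averaged under 20%. Peg10 and Sgce shared their CpGs in it, as did Peg3 and Usp29.

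The gene lists, the tests between groups, the alternatives listed first below and the rule for named features were set before the data were examined. CpGs were named as the 5 higher and 5 lower with the smallest p. Regions and gene ends were to be named as the 10 higher and 10 lower past the threshold or, with fewer than 5 past it, the 5 higher and 5 lower with the smallest p. The 3 members of each list with the smallest p were added, as were Mt1, Mt2, Mtf1, Slc39a8, Slc30a1, H19, Peg3, Snrpn, Mest, Kcnq1ot1, Dnmt1, Dnmt3a, Dnmt3l, Prm1, Prm2, Dazl, Ddx4 and Star where measured. Some genes that the rule takes are not reported here. Slc39a8, Snrpn, Dnmt1, Dnmt3a, Dnmt3l, Prm2 and Star had fewer than 3 tested CpGs at either end.

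Alternatives were minimum coverage of 5 or 20 reads, all 15 mice of each group, no dispersion term, no upper coverage limit, limma 3.58.1 on percent methylation without and with a replicate block or a coverage covariate, features with an SD of 2 points or more, separate strands, minimum differences of 5, 10 and 25 points, wider regions and other windows. Others were added after seeing the data, as were the splits of the mice and some tests of explanations. No pair of libraries of a group looked like repeat sequencing of the same library: the mean chi-square per CpG was at least 10.3 among the 210 pairs. The same DNA prepared again is not excluded by this, and pairs across the groups were not compared. On simulated beta-binomial reads with the real coverage, means and dispersions, changes were placed on features of 20 to 75% methylation, whose median SD between mice was 29.3 points for CpGs, 21.01 for regions and 18.4 for gene ends. The model called 1.5% of 200 such CpGs changed by 20 points among 100000 CpGs. It called 16% of 200 regions changed alike among 102701, beside 9 unchanged ones, and 23% of 200 such gene ends among 19066, beside 3 unchanged ones. With no change simulated, 7.72% of CpGs, 7.82% of regions and 6.49% of gene ends had an unadjusted p under 0.05, and none was called. limma called 21% of the same 200 changed gene ends. Features were simulated independently of one another, without any structure that the mice share. Other splits of the real mice called up to 341 CpGs and 660 regions. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Matplotlib 3.10.9 and R 4.3.3 were used.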

Results

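Cadmium is a toxic metal that accumulates in tissues, and the labels pose the question whether drinking it over weeks alters DNA methylation in mature sperm. Sperm DNA of 15 cadmium-treated and 15 vehicle mice was measured by RRBS. Coverage summed over cytosines averaged 67305335 ± 7264614 (SD, n = 15) in cadmium libraries and 74103801 ± 11357477 (SD, n = 15) in vehicle libraries, and the permutation test of this difference gave p = 0.0619. Among tested CpGs the median coverage was 39 reads in cadmium mice and 43.5 in vehicle mice.

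In sperm of both groups, gene ends were largely unmethylated and intergenic CpGs largely methylated. Global methylation was 28.14% ± 0.401 (SD, n = 15) in cadmium mice and 28.03% ± 0.399 (SD, n = 15) in vehicle mice. The difference of 0.112 points had an interval of -0.187 to 0.411, and p = 0.463 by the two-sided permutation test. As a share of all reads at the same CpGs, the difference was 2.01 points with an interval of -0.337 to 4.35 (p = 0.0884). That of intergenic CpGs was 2.44 points with an interval of 0.148 to 4.73 (p = 0.0309, adjusted p = 0.247). Such a share weights CpGs by their coverage and had no upper coverage limit. Over all these CpGs its SD was 3.55 points in cadmium and 2.63 in vehicle mice. The most covered cytosine held from 1.15% (cadmium mouse 9) to 10.2% (cadmium mouse 4) of a library's coverage. Whether a few deeply covered CpGs carry these differences was not tested. Gene ends averaged 4.89% ± 0.189 in cadmium and 4.84% ± 0.256 in vehicle mice. Gene bodies averaged 46.4% ± 0.911 and 46.3% ± 0.942, and intergenic CpGs 63.0% ± 0.976 and 62.7% ± 1.33, in the same order. In these means over CpGs, not as a share of reads, the widest gap among the 8 contexts was at the CpGs of 20 to 80% methylation. They stood at 51.5% ± 2.21 in cadmium and 50.6% ± 2.80 in vehicle mice, with an interval of the difference of -1.08 to 2.70 points. No context passed the test, and the smallest adjusted p of these means over CpGs was 0.945.

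**Figure D1:**
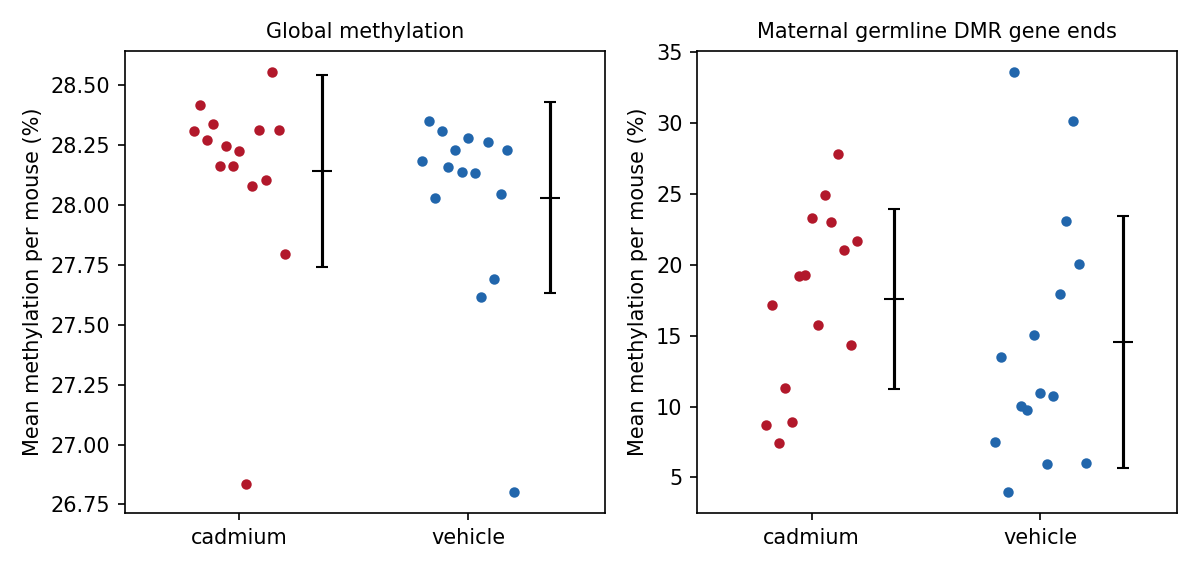
Methylation percent of each mouse, averaged over CpGs covered in every mouse (left) and over the maternal germline DMR gene ends (right), with cadmium mice in red and vehicle mice in blue; bars give the mean and SD of 15 mice, and neither vertical axis starts at 0. Global means lie at 28.14% and 28.03%, and maternal germline DMR means at 17.6% and 14.6%, with wide overlap in both panels.

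Imprinted regions were compared because germline DMRs of maternal origin are unmethylated in sperm and methylated on the maternal copy in body cells. The level over 13 gene ends, among them Peg3, Peg10, Nnat and Airn, was 17.6% ± 6.35 (SD, n = 15) in cadmium and 14.6% ± 8.87 (SD, n = 15) in vehicle mice. The difference of 3.04 points had an interval of -2.75 to 8.84, and p = 0.290. Single mice ranged from 7.45% to 27.8% in the cadmium group and from 3.97% to 33.6% in the vehicle group. Nnat, an imprinted gene of the developing brain, stood at 24.0% ± 13.2 in cadmium and 13.8% ± 11.99 in vehicle mice (p = 0.0442, adjusted p = 0.894). The H19 control region, which is methylated in sperm, on chromosome 7 at 142580146 to 142582146, was read through 2 CpGs and stood at 87.1% ± 9.32 in cadmium and 88.6% ± 12.8 in vehicle mice (p = 0.718).

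At single CpGs, 6 of 1125391 passed the threshold, 4 higher and 2 lower in cadmium mice. A CpG inside Dsn1, a gene of the kinetochore, on chromosome 2 at 157006832 to 157006833, stood at 5.44% ± 6.70 in cadmium mice and 0% in all 15 vehicle mice (adjusted p = 0.0178). It was above 0% in 7 of 15 cadmium mice, at a median coverage of 44 reads. A CpG on chromosome 11 at 5158702 to 5158703, 6380 bp from Emid1, stood at 23.3% ± 20.2 in 12 cadmium mice and 0% in 13 vehicle mice (adjusted p = 0.0428). A CpG on chromosome 4 at 26244658 to 26244659, 79847 bp from Manea, was at 100% in all 15 cadmium mice and at 89.3% ± 8.79 in vehicle mice (adjusted p = 0.0428). A CpG inside Igsf11 on chromosome 16 at 38955589 to 38955590 stood at 99.896% ± 0.182 and 97.2% ± 2.55 (adjusted p = 0.0428). The 2 lower CpGs lay on chromosome 1 at 97513040 to 97513041, 33991 bp from Gm7135, and on chromosome 12 at 57509145 to 57509146 inside Gm20016. They stood at 95.7% ± 4.35 and 91.9% ± 9.77 in cadmium mice and at 100% in every vehicle mouse measured (adjusted p = 0.0127 for both).

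CpGs inside Tiam1 (higher), Clasp2 and Gsr (lower) and 9570 bp from Psg22 (lower) came next and did not pass, at adjusted p = 0.0522. Of the 6 called CpGs, 5 had every measured mouse of 1 group at exactly 0% or 100%, where the model has no spread within that group, and 2 differed by 10 points or more. The call near Manea was lost with 20 reads or more (adjusted p = 0.0584), without the mice over 25% at maternal germline DMRs (0.0629) and without those under 27% global methylation (0.0509). Those near Emid1 (0.0629) and in Igsf11 (0.103) were lost without the mice over 25%, and that near Gm7135 with the strands kept apart (0.136); leaving out mice was chosen after seeing the data. limma called 0 CpGs, with 18324 of 1125391 at an unadjusted p under 0.05. The logistic model gave 113330 at that level, or 10.1%, against 7.72% of CpGs simulated without a change. Other splits of the mice gave 112068 to 167128 CpGs at that level in the logistic model, so the real count is no excess over them.

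Of 102701 regions, 1 passed. It held 3 CpGs on chromosome 17 at 49587948 to 49588061, 23489 bp from Daam2, and stood at 96.9% ± 3.64 in cadmium mice and at 100% in all 15 vehicle mice (adjusted p = 0.0182, median coverage 178 reads). It was below 100% in 7 of 15 cadmium mice. Regions with the next smallest p, at adjusted p = 0.104, lay at A230028O05Rik (1.67% ± 2.10 against 0%), inside Dnah8, an axonemal dynein (100% against 98.2% ± 2.30), and inside Arhgap21 (0.0775% ± 0.154 against 0.698% ± 0.427 over 55 CpGs), cadmium first in each. Regions inside Prcd, Pex14, Ano1 and Srrm3, 310683 bp from Gm40604 and 26138 bp from Gm40677 had adjusted p of 0.138 to 0.139. The regions test gave 6183 at an unadjusted p under 0.05, and limma called 0 with 3390 at that level. Other splits of the mice gave 5884 to 20567 regions at that level in the logistic model. With 20 reads or more, or all 15 mice of each group, 0 regions passed, and the called region was not among those tested. The count was 3 with 5 reads and 3 with gaps of up to 300 bp, and 8 and 4 without the mice over 25% and under 27%.

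No gene end passed among 19066 in the logistic model or in limma, with 1052 and 797 at an unadjusted p under 0.05. Other splits of the mice gave 941 to 2861 in the logistic model. Between the real groups the smallest adjusted p of a gene end was 0.300. Those higher in cadmium mice with the smallest p were Zfp212 (0.767% ± 0.464 against 0.0977% ± 0.173), Mmrn2, which encodes an endothelial matrix protein (46.6% ± 8.24 against 34.3% ± 7.36), Gm49890 (100% against 93.2% ± 10.01), the Wnt antagonist gene Frzb (3.26% ± 2.23 against 0.738% ± 0.808) and Upf3b (3.19% ± 4.81 against 0.0433% ± 0.168). The Mmrn2 window was centred on chromosome 14 at 34375504 and held 4 CpGs. Those lower were Ndufs4, a subunit of respiratory complex I (0.00884% ± 0.0342 against 0.449% ± 0.635), Mapkap1 (0.186% ± 0.300 against 0.980% ± 0.565), Npm3, Tusc2 and 4930535L15Rik. Values are cadmium against vehicle with the SD of the mice, and all but Mmrn2 and Gm49890 lay under 5%.

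Metal handling genes were near-unmethylated in both groups at the metallothioneins, which bind cadmium. Mt1, on chromosome 8 with its window centred at 94178883, stood at 3.49% ± 1.19 in cadmium and 2.66% ± 1.20 in vehicle mice (p = 0.0442, adjusted p = 0.894). Mt2 stood at 2.65% ± 1.83 and 1.45% ± 1.23, the metal-sensing transcription factor gene Mtf1 at 0.706% ± 0.755 and 1.15% ± 0.800, and the zinc exporter gene Slc30a1 at 0.472% ± 0.402 and 0.408% ± 0.266. Slc39a1, a zinc importer gene, stood at 1.02% ± 0.653 and 0.433% ± 0.494, and Abcc1 at 0.495% ± 0.419 and 0.208% ± 0.235. Of 25 measured members, 0 passed over all gene ends and 0 adjusted over the list alone, where the smallest adjusted p was 0.190. The list mean was 13.2% ± 1.98 and 13.4% ± 1.40 (adjusted p = 0.797).

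Stress and DNA damage genes averaged 0.880% ± 0.221 in cadmium and 0.737% ± 0.185 in vehicle mice, the list with the smallest unadjusted p, 0.0675. Ddit3, a stress-induced transcription factor gene, stood at 0.541% ± 0.773 and 0.158% ± 0.2204. Among oxidative stress genes, Gclc, for glutathione synthesis, stood at 0.932% ± 0.685 and 0.499% ± 0.497, Txnrd1 at 96.4% ± 3.65 and 98.5% ± 2.70, and G6pdx at 1.33% ± 3.54 and 0%. Among methylation machinery genes, the base excision repair gene Tdg stood at 0.0167% ± 0.0647 and 0.524% ± 0.885, Ahcy at 0.303% ± 0.324 and 0.736% ± 0.593, and Eed at 0.336% ± 0.472 and 0.520% ± 0.455.

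Among Hox and developmental genes, Hoxd13 stood at 1.75% ± 1.32 in cadmium and 0.754% ± 0.739 in vehicle mice and Hoxa9 at 34.2% ± 10.98 and 30.4% ± 10.03. In the steroid and testis endocrine list, Cyp11a1, which starts steroid synthesis, stood at 7.26% ± 3.30 and 4.83% ± 2.70. In the metabolic list Fasn stood at 0.870% ± 0.546 and 0.505% ± 0.475, and in the pluripotency list Esrrb stood at 56.3% ± 22.8 and 70.45% ± 21.01. Of 27 measured germ cell genes, 10 averaged under 20% and 3 over 80%. Dazl stood at 17.7% ± 8.52 and 14.2% ± 10.6, Ddx4 at 27.6% ± 10.6 and 24.9999% ± 16.7, Mael, of the piRNA pathway, at 38% ± 19.98 and 24.3% ± 21.5, and Prm1, a protamine gene, at 51.4% ± 29.4 in 14 cadmium and 64.5% ± 42.5 in 12 vehicle mice. None of the 13 lists passed, all at an adjusted p of 0.797, and no list had a member past the threshold over all gene ends or adjusted over the list alone. Among gene ends of 20 to 75% methylation, whose median SD between mice was 18.4 points, the simulations called 23% of those changed by 20 points and 2% of those changed by 10 points. Changes at gene ends of lower methylation and spread were not simulated.

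The maternal germline DMR level moved with much of the profile across the 30 mice, in both groups. It rose with mitochondrial coverage, which ran from 0.0127% to 0.119% of all coverage (r = 0.779, permutation p = 2e-05; rho = 0.780, p = 2e-05; both adjusted p = 5.5e-05 over 11 relations). It fell with methylation of the H19 control region (r = -0.578, p = 0.00086; rho = -0.496, p = 0.00552; adjusted p = 0.00189 and 0.0121). Without vehicle mice 4 and 13, the farthest from the median level, r was 0.740 and -0.447. Within groups, r with mitochondrial coverage was 0.663 in cadmium and 0.864 in vehicle mice, and r with the H19 region was -0.311 and -0.716. The first principal component of CpGs of 20 to 80% methylation, with 32.6% of the variance, followed the level (r = 0.820, permutation p = 1e-05, the smallest that the resampling can give; rho = 0.821, p = 1e-05; both adjusted p = 5.5e-05) and gave p = 0.757 between the groups. Its r was 0.751 without the same vehicle mice, 0.625 within cadmium and 0.934 within vehicle mice. The level showed no passing relation with the unmethylated control (r = -0.0937, p = 0.621, rho = -0.0621, p = 0.743) or total coverage (r = 0.135, p = 0.474, rho = 0.0558, p = 0.768). The same held for global methylation (r = 0.144, p = 0.452, rho = 0.0501, p = 0.791) and mitochondrial methylation (r = 0.0104, p = 0.957, rho = -0.00245, p = 0.991).

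**Figure D2:**
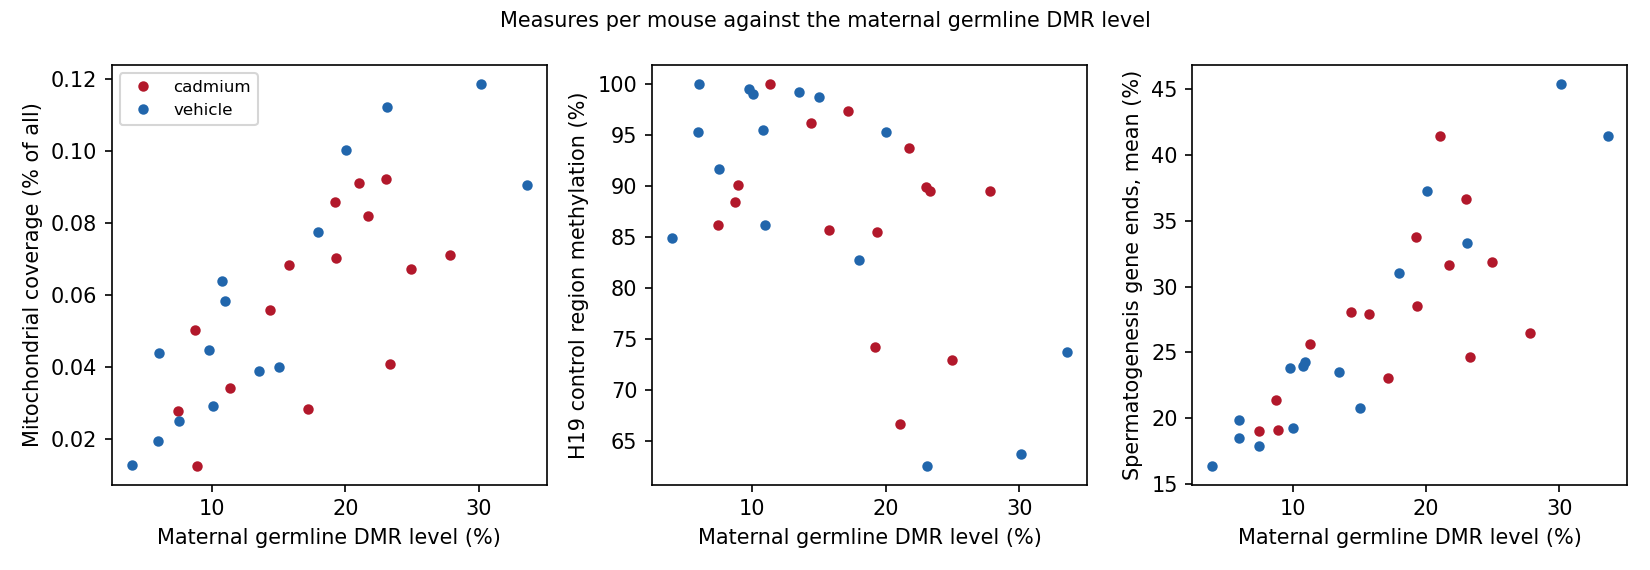
Mitochondrial coverage in percent of all coverage (left), H19 control region methylation in percent (middle) and mean methylation of spermatogenesis gene ends in percent (right) against the maternal germline DMR level in percent; each point is 1 mouse, cadmium in red and vehicle in blue. Spearman rho over the 30 mice is 0.780, -0.496 and 0.859 from left to right.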

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

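Global methylation and the imprinted regions kept their direction and stayed short of the threshold under the 6 and 4 alternatives reported here, which leave out the withdrawn comparisons named below. The global difference ranged from 0.112 to 2.01 points, the highest as a share of reads, which weights CpGs by their coverage (p = 0.0884). The alternatives that left out mice, used both gene ends or took the maternal level as a covariate were chosen after seeing the data. Mice were left out for a maternal germline DMR level over 25% (3 mice) or global methylation under 27% (2 mice), and comparisons of the measure that picked them, run without them, were withdrawn as circular after their values had been seen. At least 1 of these had passed an unadjusted p of 0.05, the maternal germline DMR level without the 3 mice over 25%, with a wider difference in the same direction. It is not used, since the level picked the mice. The cause of each change below was not tested. Windows at the 5′ end of every transcript and exon and intron contexts were not run, for lack of strand and exons.

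Called CpGs numbered 484052 without a dispersion term, 11 among those with an SD of 2 points or more, 14 with 5 reads or more, 2 with a difference of 10 points and 0 with 25 points. limma called 0 CpGs plain, 0 with the coverage covariate and 0 with the maternal level. Regions numbered 59618 without a dispersion term, 3 with 5 reads, 0 with 20 reads, 0 with all 15 mice, 8 without the mice over 25% and 4 without those under 27%, 3 with gaps up to 300 bp, and 0 in limma plain or with either covariate. Gene ends numbered 10519 without a dispersion term and 1, A830092H15Rik, without the mice under 27% (1.75 points, adjusted p = 0.0179), named after its values were seen.

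The shared replicate numbers were not taken to pair the mice, since 6 of 15 pairs had a correlation over 0.1, from -0.269 to 0.694, and 2 of 15 cadmium mice correlated best with their own number. The mean was 0.113 for same-numbered pairs and -0.00668 for others. The first principal component lay on the same side of 0 in both groups for 10 of 15 numbers (below in 1, 2, 3, 5 and 8, above in 10 to 14) and on opposite sides for 5 (4, 6, 7, 9 and 15). This was not tested, and a structure shared by number is not excluded. The replicate block left 0 CpGs, 0 regions and 0 gene ends in limma and 0.11199 points of global methylation (p = 0.407).

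Differences short of the threshold changed sign as follows, in points. Without the mice over 25%: gene bodies -0.0623, pluripotency list 1.03, Inha -0.00537, Lcn9 -1.87. By share of reads: low CpGs -0.0713, metal handling 0.231, oxidative stress 0.0228, pluripotency 0.506, epididymal epithelium 0.328, leukocytes -0.521. With 20 reads: X -0.0674, Inhbb -0.0442. With 2000 bp outside and 500 bp inside: metal handling 0.115, pluripotency 0.754, Inpp5f -0.762, Sox2 0.177, Cldn4 -1.95, Lcn9 -0.255. Without the mice under 27%: metal handling 0.0264, oxidative stress 0.00168. With all 15 mice: Inhbb -0.121, Pparg -0.213, Mt2 -0.0131. With 5 reads: Prm1 3.14. With the maternal level: Ddx4 -1.88. Wider regions put the Ano1 region at 1.11 and windows at 0.860, and both put the Srrm3 region at 0.188.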

Other observations

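The tests of body cell DNA, bisulfite conversion and treatment as causes, the counts over splits of the mice, and the comparisons with matched gene ends, were chosen after the results were seen; those of germ cell genes, cell type lists and strands were set before. Across the 30 mice, methylation of germ cell genes followed the maternal germline DMR level. The mean over the 26 spermatogenesis gene ends measured in every mouse rose with it (r = 0.839, permutation p = 1e-05; rho = 0.85851, p = 1e-05, the smallest that the resampling can give; both adjusted p = 5.5e-05 over 11 relations). The r was 0.776 without vehicle mice 4 and 13, 0.631 within cadmium and 0.945 within vehicle mice. Of 27 members, 15 rose and 1 fell by rho, adjusted over 43 gene ends of 4 lists. Dazl ranged from 2.81% to 35.7% methylation, Ddx4 from 3.39% to 58.1%, and the synaptonemal complex genes Sycp1 and Sycp3 from 8.004% to 67.9% and from 0% to 69.8%. Prm1 fell with the level (rho = -0.730 in the 26 mice where it was measured). Genes low in every mouse, such as Crem, Kit and Odf2, did not pass. Nor did the highly methylated Izumo1 (94.2%), Tssk1 (92.1%) and Spata16 (83.9%). Lists of random gene ends matched on mean methylation rose too, with a median rho of 0.794, and 6.57% of 10000 had a rho as high, so the list does not stand apart from other gene ends of like methylation.

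The level itself varied as much among vehicle mice as among all mice, with a ratio of SDs of 1.1463, which argues against cadmium as the whole cause; a part set by treatment stays open. Incomplete conversion would add methylation everywhere, and the H19 control region fell instead (rho = -0.49616). DNA of body cells in the sperm samples is a candidate explanation: mitochondrial coverage rose with the level (rho = 0.7802). Both also ran with replicate number. In cadmium mice 1 to 5 the level was 7.45% to 17.2% and mitochondrial coverage 0.0127% to 0.0502%. In cadmium mice 6 to 15 they were 14.4% to 27.8% and 0.0409% to 0.0923%. Vehicle mice ran less evenly, with 33.6% and 0.0906% in vehicle mouse 4. A cause shared by number was not tested. Whether germ cell genes rose as genes methylated in body cells and not in sperm stays open (rho = 0.85851). The matched lists cannot decide it, since they were matched on methylation in these same mice and could rise for the same reason. The labels describe washing of sperm and name no lysis of other cells. No pure body cell sample was analysed here, so no share was estimated.

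Which cells these might be is open in part, and of the 17 genes listed for epididymal epithelium 1 is in another list. Gene ends of the epididymal epithelium list, which would be unmethylated in that epithelium, fell as the level rose (r = -0.700, permutation p = 2e-05; rho = -0.70857, p = 2e-05; both adjusted p = 5.5e-05). The r was -0.571 without vehicle mice 4 and 13, -0.480 within cadmium and -0.854 within vehicle mice. Of 8 members 3 fell, Lcn5, Lcn9 and Rnase10, while Epcam at 88.3% and Krt18 at 2.10% did not pass. CpGs over 80% methylation fell as well (r = -0.752, permutation p = 4e-05, rho = -0.751, p = 2e-05, a single relation tested after the others). Their r was -0.651 without the same mice, -0.535 within cadmium and -0.892 within vehicle mice. Of 10000 lists of gene ends matched on mean methylation, 6.31% had a rho as low as the epididymal list, so this cell type stays open. Leukocyte genes (rho = 0.085651, permutation p = 0.654, 3 members) and fibroblast, muscle and vessel genes (rho = 0.043826, p = 0.818, 5 members) leave their cells open. Few members were measured. Leukocyte gene ends averaged 0.566% to 6.69%, and those of the second group apart from Tagln 0.877% to 4.26%. They had little room to fall, so these lists could hardly show the fall looked for. Tagln, the most methylated of the second group at 16.5%, had rho = 0.195.

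Without a dispersion term, 484052 of 1125391 CpGs passed, and 75 of 100 splits of the 30 mice, the real one included, gave as many, the highest other 552576, so chance was not excluded. Within-group variance was 18.4 times the binomial value on 1 strand of 3193 CpGs of 20 to 80%. These CpGs had 10 or more reads on each strand in every mouse. The binomial value was taken at each mouse's own percent and not at the group mean. It shrinks where a mouse lies near either end of the scale, so the ratio can overstate the excess. Over all tested CpGs, both strands summed, the median dispersion was 6.62. The strands of a CpG shared only a part of a mouse's deviation (pooled correlation 0.31942 over 3193 CpGs, jackknife SE 0.00474). This argues against stable differences between mice as the whole cause. Few DNA molecules behind the reads of a CpG may account for the rest, and a shared part, in which body cell DNA could take a share, stays open.

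Chance was not excluded for the CpGs and regions called with the dispersion term either. As many CpGs as the 6 called came from 63 of 100 splits, the real one included, the highest other 341. As many regions as 1 came from 76 of 100 splits, counted alike, the highest other 660. The real split called 0 gene ends, so that 100 of 100 splits reach it says nothing about chance, and the highest other was 6. Splits that called many more than the real one point to a structure of the mice other than treatment.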
